A study of Rattus norvegicus with 24 samples.

How the data were processed

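Expression was measured on Affymetrix rat arrays in cerebellum and hippocampus of Long-Evans pups at postnatal day (PND) 7 and 14, after their mothers had received Aroclor 1254, a commercial mixture of polychlorinated biphenyls, at 0 or 6 mg/kg/day from gestation day 6. There are 24 arrays in 8 groups (tissue, age and dosing) with 3 arrays in each. Per the labels, the number in each title names the mother, and 1 male pup was taken per litter at each age. The 6 mothers are 3 undosed dams (1, 7 and 13) and 3 dosed dams (12, 15 and 18), so dosing p-values rest on 3 dams per group, or on 2 undosed dams for cerebellum at PND14 where the array of dam 13 is left out. The values deposited by the authors are log2 expression values per probe set, read as log2 from their range. The software, background correction, summary method and between-array normalization that made them are not given in the sources used here. In 23 of the 24 columns the medians lay within 7.423 to 7.484, while the cerebellum PND14 undosed array of dam 13 had a median of 7.911 and a different lowest value.

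Of 15923 probe sets, 57 control probe sets were left out. The platform table that comes with the series gave 1 gene symbol for 12783 of the remaining 15866, several for 312 and none for 2771. Of those with 1 symbol, 12748 matched a RefSeq gene through their Entrez number and 0 symbols changed. Genome positions are not used here. Because the column medians differed by more than 0.2, the values were quantile normalized with limma 3.58.1 in R 4.3.3, by a rule set before the data were examined. Probe sets above the 40th percentile of an array in at least 3 arrays were tested, which left 10417 probe sets and 7527 genes with a symbol. A gene with several probe sets is represented by the one with the highest mean.

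Limma was fitted with 1 mean per group over all 24 arrays, followed by empirical Bayes moderation, and 2-sided p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested. Probe sets with an adjusted p under 0.05 are called, and only called genes are said to have risen or fallen. Errors of a change are limma standard errors (SE), and errors of a group are standard deviations (SD) over 3 arrays unless another n is given. The 15 comparisons are dosed against undosed pups in each tissue and age, the dosing effect averaged over tissues and ages from 1 mean per dam, PND14 against PND7 in each tissue and dosing group, the differences of the dosing effect between ages and between tissues, and cerebellum against hippocampus in undosed pups at each age. The comparisons, filter, normalization rule, gene lists, fixed genes, naming rule and most other settings compared were chosen before the data were examined.

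Genes are named by a rule. For dosing, these are the 10 largest rises and 10 largest falls among called genes whose 2 groups do not overlap, filled to 5 by the smallest unadjusted p where fewer pass. For age in undosed pups the rule takes 12 in each direction, and for tissue and for differences between dosing effects it takes 5. A set of 27 fixed genes and the 4 members with the largest change of each list that passes are added. Other genes named are said to have been chosen after their values were seen. The 31 lists with at least 3 measured genes hold markers of cell types and members of pathways. They were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry, adjusting over the lists of a comparison. The number of members called when p is adjusted over the list alone is given beside the number called over all probe sets. Of 115 list calls made by camera, 0 had a median of another sign with the values as deposited.

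The numbers pair the arrays of a mother because the labels say so. Deviations from the group mean correlated between the 2 tissues of one dam at one age with a median r of 0.28 over 11 pairs, and between the 2 ages of one dam in one tissue with a median r of 0.01, where the pups differ. Fits with the dam as a block were run as alternatives. The others were no filter, a stricter filter at the 60th percentile, the values as deposited, an intensity trend in the variance prior, only the arrays of 1 tissue, only the 6 arrays compared, and each replicate left out in turn. After the data were seen, fits without the array of dam 13 were added for comparisons that do not include its group, the dosing average and the gene lists. Fits without it together with 4 arrays of high Xist or with the PND14 arrays of dam 15 were added too.

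The code was tested on simulated data with 200 probe sets changed by known amounts, built from the overall mean and within-group spread of each real probe set, with no other differences between groups. For changes of 0.5, 1 and 2 on the log2 scale it recovered 46.3%, 73.1% and 87.9% for dosing in cerebellum at PND7 (10289 probe sets tested), 37.3%, 77.6% and 92.4% at PND14 (10285), 49.3%, 68.7% and 83.3% in hippocampus at PND7 (10292) and 46.3%, 73.1% and 87.9% at PND14 (10292). The dosing average gave 61.2%, 80.6% and 92.4% (10301). For age the shares were 38.8%, 77.6% and 86.4% in undosed cerebellum (10281), 29.9%, 82.1% and 92.4% in dosed cerebellum (10284), 35.8%, 70.1% and 74.2% in undosed hippocampus (10293) and 37.3%, 76.1% and 90.9% in dosed hippocampus (10288). Differences of the dosing effect gave 17.9%, 71.6% and 89.4% between ages in cerebellum (10280), 16.4%, 53.7% and 80.3% between ages in hippocampus (10282), 14.9%, 56.7% and 89.4% between tissues at PND7 (10264) and 19.4%, 56.7% and 83.3% at PND14 (10281). Tissue gave 20.9%, 89.6% and 87.9% at PND7 (10289) and 34.3%, 77.6% and 83.3% at PND14 (10289). With the array of dam 13 left out the shares rose to 82.1%, 98.5% and 100% for dosing in hippocampus at PND7 (9948), 80.6%, 100% and 100% in cerebellum at PND7 (9948) and 43.3%, 97.0% and 98.5% for the difference between ages in hippocampus (9961). Between 2 and 13 unchanged probe sets were called in each simulated comparison. When 1 list was lowered by 0.5 in dosed hippocampus at PND7 it was the 1 list of 31 called. The simulated noise was independent between probe sets, so this cannot show how correlation between list members affects list calls.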

Results

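The series holds 24 arrays, 3 in each of 8 groups made by tissue (cerebellum or hippocampus), age (PND7 or PND14) and dosing of the mother with Aroclor 1254 (0 or 6 mg/kg/day). It addresses how this mixture of polychlorinated biphenyls changes gene expression in the developing brain. Group mates correlated with r between 0.986 and 0.996 in 23 arrays. The cerebellum PND14 undosed array of dam 13 correlated with every other array at 0.623 to 0.659, while the lowest r between any 2 of the other 23 was 0.941. In that array 96 probe sets shared the lowest value of 5.07. The array stayed in the 24-array fit, and counts without it are given for every comparison, with values without it for some of the genes and lists whose call it changes.

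**Figure D1:**
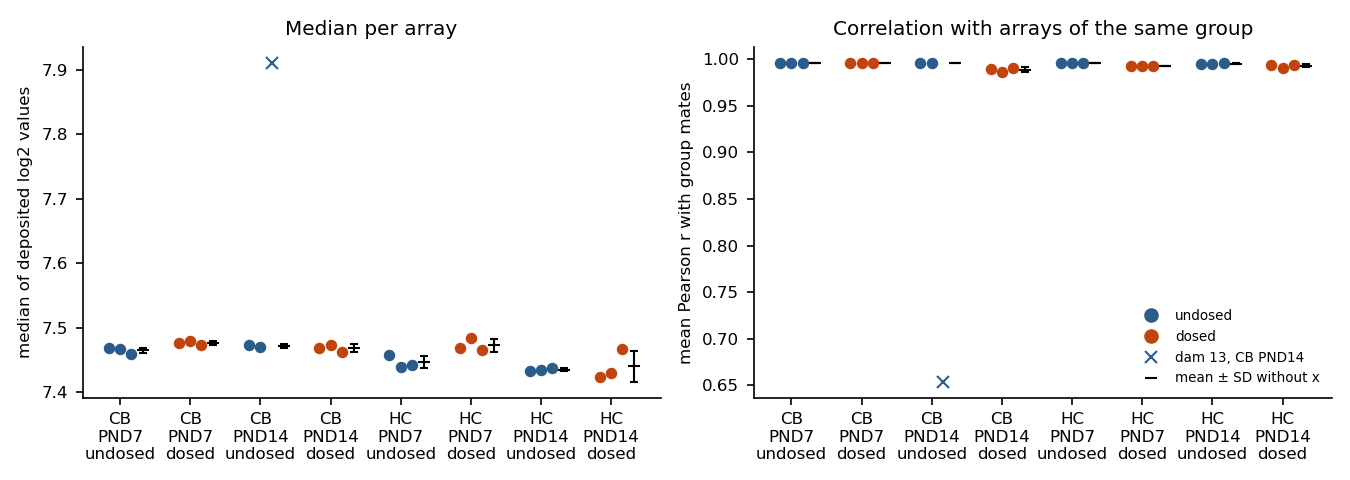
Median of the deposited log2 values (left) and mean Pearson r with group mates (right) for each of 24 arrays, by group (CB cerebellum, HC hippocampus), with the group mean and SD drawn without the array marked x. The marked array, dam 13 in undosed cerebellum at PND14, has a median of 7.911 against 7.423 to 7.484 in the others.

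In hippocampus at PND7 the gene closest to a call after dosing, Pgpep1, was lower in dosed pups. Several connective tissue genes, further from a call, were lower too. Pgpep1, a peptidase that trims the first residue of neuropeptides, had a log2 change of -0.97 ± 0.15 (SE, 3 dams per group, adjusted p = 0.0671), from means of 8.05 ± 0.24 (SD) in undosed to 7.08 ± 0.23 in dosed pups. Lum encodes lumican, a proteoglycan that binds collagen, and changed by -1.08 ± 0.23 (adjusted p = 0.176), with all 3 dosed pups below all 3 undosed pups. The dosed pups had Lum at 5.46 to 5.91, a low signal that limits this change. Cyp1a1, which did not pass the filter on low values, had higher group means of 6.24 to 6.46. Col1a2, a chain of type I collagen, changed by -0.77 ± 0.29, Slc6a13, a GABA transporter of the meninges, by -0.75 ± 0.25, and the growth factor Igf2 by -0.76 ± 0.28. Limma called 0 probe sets over 24 arrays, while 669 had an unadjusted p under 0.05 against 521 expected by chance. The same 521 holds for each comparison over 24 arrays. Single dosing comparisons ran from 101 in hippocampus at PND14 to 2001 in cerebellum at PND14. Without the array of dam 13 these became 392 and 503, against 516 expected. The 24-array counts can thus not be read against the number expected by chance. Without the array of dam 13, which belongs to neither group, limma called 62, of which 24 rose and 38 fell, with 1761 at an unadjusted p under 0.05 out of 10330 tested. The 62 rest on quantile normalized values, and this fit was not repeated with the values as deposited. That count changed with other arrays left out too. It was 3, all lower, when 4 arrays of high Xist were also left out, which leaves fewer undosed pups. It was 247 when the PND14 arrays of dam 15 were left out instead. With only the array of dam 13 left out, Lum fell by 1.09 ± 0.17 (adjusted p = 0.0141) and Pgpep1 fell by 0.98 ± 0.14 (adjusted p = 0.0134). Cmtm7, which encodes a membrane protein of immune cells, rose by 0.54 ± 0.11 (adjusted p = 0.0276). Genes chosen after their values were seen in that fit include Cdkn1c, an imprinted inhibitor of the cell cycle, which fell by 1.16 ± 0.24. The transcription factors Meis2 and Nr2f2 fell by 1.14 ± 0.23 and 0.80 ± 0.16, the proteoglycan Dcn fell by 0.56 ± 0.12, and the aldehyde reductase Akr7a3 rose by 0.57 ± 0.12.

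Of 19 genes of meninges and fibroblasts measured in hippocampus at PND7, 18 were lower in dosed pups and 1 was higher, with a median log2 change of -0.42. Camera gave an adjusted p of 5.02e-10 for the list, and adjusted p = 0.0716 with an estimated correlation. Over 24 arrays 0 of the 19 were called over all probe sets and 2 when adjusted over the list alone. Leaving out the array of dam 13 made these counts 2 and 9, and the list gave 1.24e-08, or adjusted p = 0.418 with an estimated correlation. All 10 choroid plexus genes measured were lower (adjusted p = 0.0264; adjusted p = 0.994 with an estimated correlation), as were 29 of 38 ribosomal protein genes (adjusted p = 0.0222; adjusted p = 0.994 with an estimated correlation), with 0 of either called when adjusted over the list alone. When that array was left out the choroid plexus list gave 0.0963 and the ribosomal list 0.0645.

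In cerebellum at PND7 genes of meninges and choroid plexus were again lower in dosed pups, and genes of Purkinje cells were slightly higher, though none was called. Col1a2 had means of 10.37 ± 0.25 in dosed and 10.73 ± 0.23 in undosed pups (SD, n = 3). Sostdc1 and Enpp2, both abundant in choroid plexus, changed by -0.80 ± 0.52 and -0.81 ± 0.49. Car8, a protein that tunes calcium release in Purkinje cells, changed by 0.23 ± 0.11, and Atp1b2, a sodium pump subunit of glia, by 0.36 ± 0.09. The smallest adjusted p was 0.895, for Hsd17b8, a mitochondrial dehydrogenase, at -0.31 ± 0.06. Limma called 0 probe sets, with 153 at an unadjusted p under 0.05, and 0 without the array of dam 13, with 543. All 19 meningeal genes were lower (camera adjusted p = 3.08e-06; adjusted p = 0.127 with an estimated correlation), as were all 10 choroid plexus genes (adjusted p = 1.98e-06; adjusted p = 0.151 with an estimated correlation). Of 14 Purkinje cell genes 12 were higher, with a median of 0.11 (adjusted p = 3.82e-04; adjusted p = 0.0287 with an estimated correlation). Leaving out that array of dam 13 gave the Purkinje list adjusted p = 0.117 with an estimated correlation. Synaptic vesicle genes were higher in 26 of 33 (adjusted p = 0.00343; adjusted p = 0.127 with an estimated correlation) and GABA and glycine genes in 14 of 20 (also 0.00343 and 0.127). All 4 red cell genes were lower (adjusted p = 0.0276; adjusted p = 0.424 with an estimated correlation), and the list gave 0.173 when the array of dam 13 was left out. In none of these lists was a member called, over all probe sets or adjusted over the list alone.

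Polychlorinated biphenyls can act through the aryl hydrocarbon receptor and related sensors, and of 27 genes listed as induced by those 9 were measured, of which 0 were called in any dosing comparison. In cerebellum at PND7, 8 of the 9 were lower in dosed pups (camera adjusted p = 0.0208; adjusted p = 0.424 with an estimated correlation), while in hippocampus at PND14 6 of the 9 were higher (adjusted p = 0.0872), with 0 called in either when adjusted over the list alone. Cyp1b1, a cytochrome the receptor induces, changed by -0.22 ± 0.15 there, by -0.02 ± 0.15 in hippocampus at PND7, by 0.16 ± 0.15 in cerebellum at PND14 and by 0.14 ± 0.15 in hippocampus at PND14. Cyp1a1, the most inducible of these enzymes in liver, did not pass the filter on low values, and its group means were 6.24 to 6.46. Klf9, a transcription factor that thyroid hormone induces in brain, changed with dosing by -0.12 ± 0.13 in hippocampus at PND7 and by 0.08 ± 0.13 in cerebellum at PND14.

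In hippocampus at PND14 haemoglobin genes were higher in dosed pups, though none was called. The smallest adjusted p, 0.36, was that of 2 probe sets shared by the alpha haemoglobin genes Hba-a1 and Hba-a2, chosen after their values were seen, with changes of 1.09 ± 0.20 and 1.00 ± 0.19. Hbb, a haemoglobin chain, was higher by 1.35 ± 0.34 (adjusted p = 1), with means of 12.21 ± 0.51 in dosed and 10.85 ± 0.45 in undosed pups and all 3 dosed pups above all 3 undosed pups, the highest being the pup of dam 15 at 12.8. The choroid plexus gene Ttr was higher there without overlap too, at 8.61 ± 0.29 against 7.30 ± 0.53, a change of 1.31 ± 1.69 with its spread over all groups. Alas2, which starts haem synthesis in red cell precursors, was higher by 1.05 ± 0.57. The vessel wall genes Eln (elastin) and Myh11 (smooth muscle myosin) changed by -0.49 ± 0.14 and -0.51 ± 0.14, and Sgk1, a kinase that glucocorticoids induce, by 0.36 ± 0.17. Limma called 0 probe sets, with 101 at an unadjusted p under 0.05, and 0 without the array of dam 13, with 392. The 4 red cell genes gave a camera adjusted p of 0.00608 (adjusted p = 0.456 with an estimated correlation), with 2 of them higher, 2 lower and 1 called higher when adjusted over the list alone. Glucocorticoid and clock genes were higher in 13 of 15 (adjusted p = 3.16e-04; adjusted p = 0.456 with an estimated correlation), and cholesterol synthesis genes were lower in 16 of 19 (adjusted p = 0.0307; adjusted p = 0.829 with an estimated correlation). Of these 2 lists, 0 members were called when adjusted over the list alone.

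In cerebellum at PND14 several large changes came from the array of dam 13. Dcx, a protein of migrating young neurons, had a log2 change of 2.02 ± 0.95 over 24 arrays and 0.02 ± 0.14 without that array, where the undosed group has 2 arrays. Gfap, the intermediate filament of astrocytes, changed by 1.80 ± 0.95 with it and by -0.13 ± 0.27 without. Mki67, a marker of dividing cells, changed by -0.62 ± 0.20 and -0.49 ± 0.20, and Nup50, a nuclear pore protein, by -0.55 ± 0.13 and -0.48 ± 0.14. Limma called 0 probe sets, with 2001 at an unadjusted p under 0.05 and a smallest adjusted p of 0.239. Without the array it called 0 again, with 503. No list passed over 24 arrays. Without the array 36 cell cycle genes had a median of -0.20 (camera adjusted p = 7.19e-12; adjusted p = 0.338 with an estimated correlation) and 0 were called when adjusted over the list alone.

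**Figure D2:**
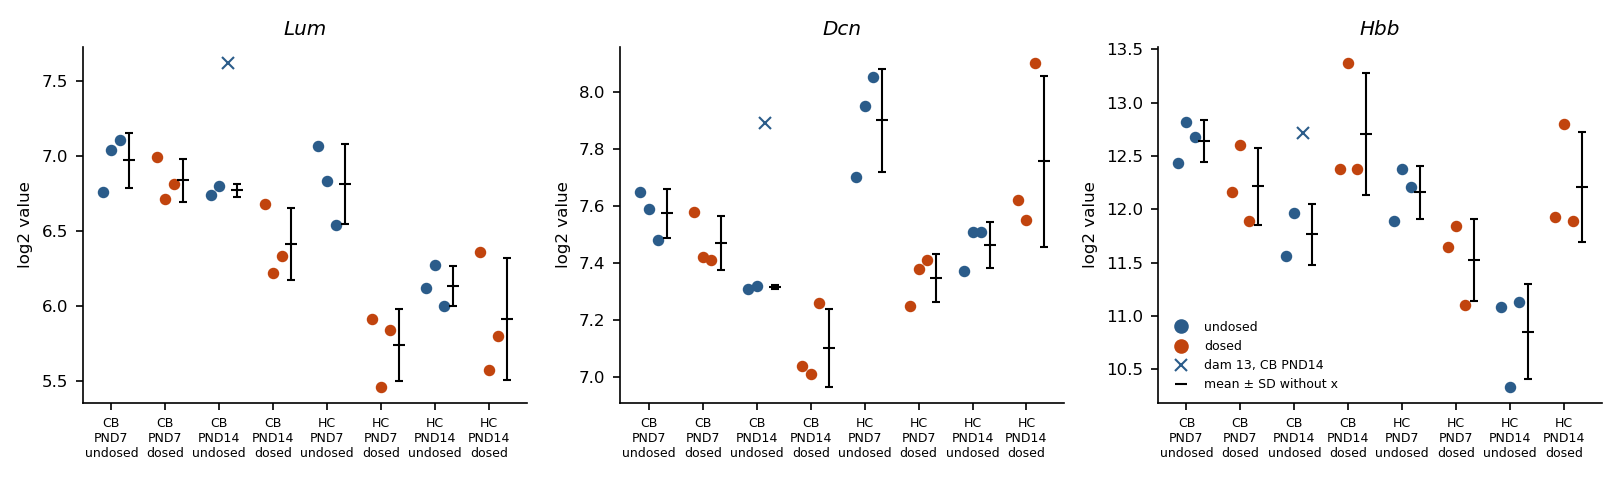
Log2 values of Lum, Dcn and Hbb per array in the 8 groups (CB cerebellum, HC hippocampus), undosed in blue and dosed in orange, with the mean and SD drawn without the array marked x. In hippocampus at PND7 the dosed pups lie at 5.46 to 5.91 for Lum and the undosed pups at 6.54 to 7.07.

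Averaged over both tissues and ages per dam, several connective tissue genes were lower in dosed pups, but this average includes the PND7 arrays already described. Without the array of dam 13, the mean of the 19 meningeal genes in hippocampus was 8.11 in dosed and 8.57 in undosed pups at PND7. At PND14 these were 7.91 and 7.98 (log2). In cerebellum the dosed and undosed means were 8.65 and 8.89 at PND7, and 8.28 and 8.33 at PND14. Lgals1, a galectin abundant in meninges, changed by -0.40 ± 0.07 (3 dams per group, adjusted p = 0.892), Col1a2 by -0.48 ± 0.11, Lum by -0.52 ± 0.13 and the vascular transcription factor Nr2f2 by -0.25 ± 0.05. Limma called 0 probe sets, with 138 at an unadjusted p under 0.05, and 0 without the array of dam 13, with 371. Of the 19 meningeal genes 17 were lower (camera adjusted p = 3.78e-08; adjusted p = 0.0843 with an estimated correlation; fry adjusted p = 0.00679), and 5 fell when adjusted over the list alone. Without the array the list gave 1.65e-17, adjusted p = 0.0308 with an estimated correlation and fry adjusted p = 0.00738, with 9 lower calls when adjusted over the list alone. The choroid plexus list gave 0.00188 (adjusted p = 0.27 with an estimated correlation), with 0 called over the list alone.

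The question whether dosing acted differently at the 2 ages or in the 2 tissues was tested directly. Qpct, an enzyme that forms pyroglutamate on peptides, had in hippocampus a dosing effect that at PND14 exceeded the one at PND7 by 1.24 ± 0.26 (adjusted p = 0.319). Socs6, a brake on cytokine signalling, differed by 0.70 ± 0.15 and Dcn by 0.85 ± 0.21. When the array of dam 13 was left out limma called 14 probe sets there, 13 higher and 1 lower, with Qpct at 1.26 ± 0.25 (adjusted p = 0.0478) and Dcn at 0.85 ± 0.16 (adjusted p = 0.0466). Of these 14, 3 are probe sets shared by Hba-a1 and Hba-a2, chosen after their values were seen, whose 24-array adjusted p was 0.24, 0.24 and 0.383. Over 24 arrays it called 0 in each of the 4 tests, with 517 at an unadjusted p under 0.05 for hippocampus by age, 701 for cerebellum by age, 516 for tissue at PND7 and 312 for tissue at PND14. Without the array the other 3 tests gave 0 calls, with 695, 1459 and 266. At PND7 the dosing effects of Atp1b2 differed between the tissues by 0.61 ± 0.13 (adjusted p = 0.289). In cerebellum the dosing effects on Nup50 differed between ages by -0.82 ± 0.18 (adjusted p = 0.524), and at PND14 those of Mdm2, which restrains p53, differed between tissues by -0.62 ± 0.18 (adjusted p = 0.624). A list passed in neither test between tissues.

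From PND7 to PND14 the undosed cerebellum gained genes of mature granule and Purkinje cells and lost genes of dividing precursors. Gabra6, a GABA receptor subunit of mature granule cells, rose by 3.97 ± 0.26, from 6.65 ± 0.13 to 10.61 ± 0.14 (SD, n = 3 arrays, adjusted p = 1.09e-08). Pvalb, a calcium buffer of Purkinje cells and interneurons, rose by 4.04 ± 0.21, and Slc17a7, a vesicular glutamate transporter, by 2.22 ± 0.15. Klf9 rose by 1.97 ± 0.13, Mbp, a main protein of myelin, by 1.67 ± 0.27, and the thyroid hormone target Hr by 1.72 ± 0.24. Mki67 fell by 0.95 ± 0.20 and Ccnd1, a cyclin of precursors, fell by 1.66 ± 0.24. Limma called 2537 probe sets, of which 1638 rose and 899 fell. Without the array of dam 13, which belongs to the PND14 group, 1563 rose and 1792 fell. With the values as deposited the share of calls that rose was 76.6% against 64.6%, and the median of all probe sets was 0.16 against 0.03. Called falls of more than 2-fold numbered 241 over 24 arrays and 79 without that array. Some large falls shrank, such as that of Crip2, a LIM protein, from -2.97 ± 0.72 to -1.46 ± 0.11. Calm2 and Cox8a, negative over 24 arrays, changed by 0.36 and 0.40 without the array. Ttr, the thyroid hormone carrier of choroid plexus, fell by 4.77 ± 1.69 (adjusted p = 0.0472) and was not called without it, at -3.24 ± 1.60 (adjusted p = 0.129).

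Among 36 cell cycle genes in undosed cerebellum 34 fell, 0 rose and 2 did not pass (camera adjusted p = 1.57e-17; adjusted p = 0.0167 with an estimated correlation), with 34 called over the list alone. Of 12 genes of granule cell precursors 8 fell (adjusted p = 5.08e-04), and of 19 genes of mature granule cells 13 rose and 0 fell (adjusted p = 2.07e-08), with 8 and 14 called when adjusted over the list alone. Of 14 Purkinje cell genes 12 rose, among them Pcp2 by 1.23 ± 0.11 and Itpr1, the calcium release channel of these cells, by 0.88 ± 0.10, and 1 fell (adjusted p = 4.77e-09). Of 25 genes known to respond to thyroid hormone 12 rose and 1 fell (adjusted p = 5.85e-06). Of 33 synaptic vesicle genes 20 rose (adjusted p = 1.2e-08), and of 50 calcium signalling genes 30 rose and 1 fell (adjusted p = 5.21e-10). Adjusted over the list alone, 12 rose in each of the Purkinje and thyroid hormone lists, 21 among vesicle genes and 33 among calcium genes. These 7 lists passed with an estimated correlation, the largest of those adjusted p being 0.0218. Of 18 myelin genes 12 rose (adjusted p = 1.28e-04; adjusted p = 0.265 with an estimated correlation), and of 38 ribosomal protein genes 18 fell (adjusted p = 7.76e-10; adjusted p = 0.113 with an estimated correlation), with 12 and 28 called over the list alone.

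In dosed cerebellum the same comparison gave Gabra6 a rise of 3.21 ± 0.26 (3 arrays per age, adjusted p = 1.84e-07), Klf9 of 2.01 ± 0.13 and Pcp2 of 1.23 ± 0.11. Mki67 fell by 1.72 ± 0.20 and Mbp rose by 1.37 ± 0.27. Limma called 1771 probe sets, with 879 risen and 892 fallen, and 3590 without the array of dam 13, which is in neither group but enters the normalization, the filter and the shared estimate of spread. Cell cycle genes fell in 27 of 36, and mature granule cell genes rose in 12 of 19, with 31 and 13 called when adjusted over the list alone and estimated-correlation adjusted p of 0.00404 and 0.00179. The thyroid hormone list had 12 risen and 1 fallen of 25 (adjusted p = 2.15e-05; adjusted p = 0.0256 with an estimated correlation), with 13 and 1 over the list alone. Dosed and undosed cerebellum shared 774 rises, where 138 would overlap if the calls were independent, and 472 falls against 77, with 0 in opposite directions.

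**Figure D3:**
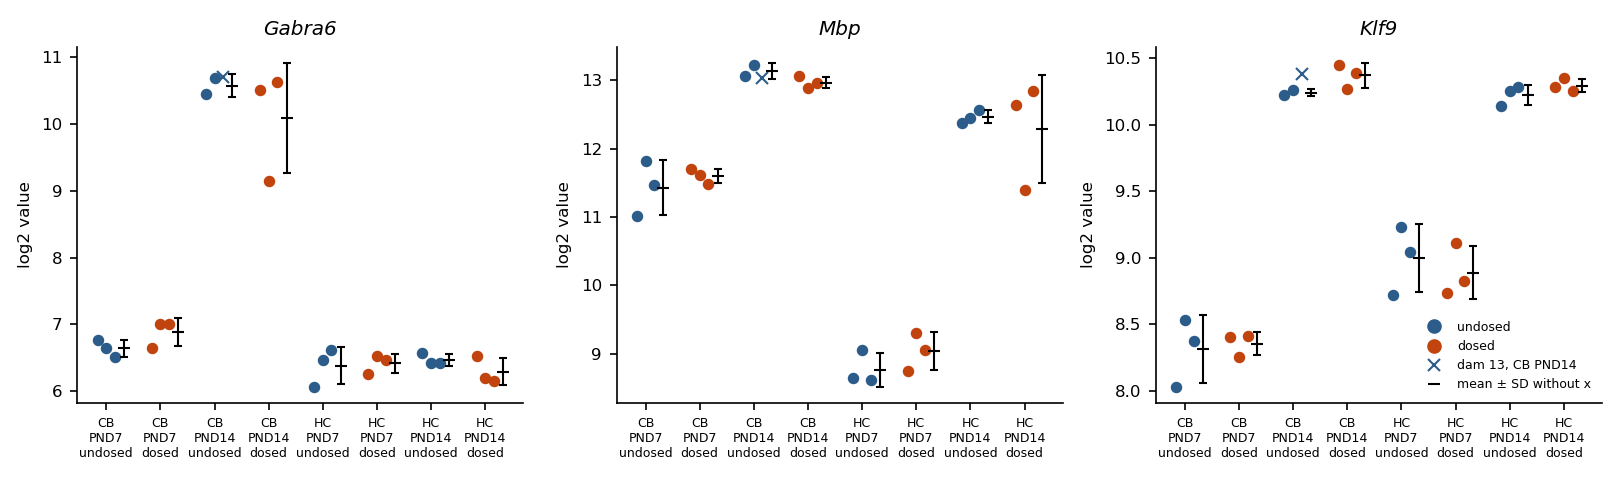
Log2 values of Gabra6, Mbp and Klf9 per array in the 8 groups (CB cerebellum, HC hippocampus), undosed in blue and dosed in orange, with the mean and SD drawn without the array marked x. Gabra6 in undosed cerebellum lies at 6.51 to 6.77 at PND7 and 10.45 to 10.7 at PND14.

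In undosed hippocampus the week from PND7 to PND14 brought myelin and synaptic genes up and genes of young migrating neurons down. Mbp rose by 3.70 ± 0.27, from 8.77 ± 0.25 to 12.47 ± 0.10 (SD, n = 3 arrays, adjusted p = 3.27e-07), Mobp, another myelin protein, by 3.33 ± 0.58 and Mag, an adhesion protein of myelin, by 2.71 ± 0.31. Camk2a, a kinase of excitatory synapses, rose by 1.60 ± 0.34, Klf9 by 1.23 ± 0.13 and the activity-induced gene Arc by 1.32 ± 0.23. Gpc2, a proteoglycan of growing axons, fell by 1.68 ± 0.14, Tnc, a matrix glycoprotein, fell by 1.61 ± 0.30, and Reln, which guides neuronal layering, fell by 0.49 ± 0.10. Hbb fell by 1.31 ± 0.34. Limma called 1452 probe sets, with 678 risen and 774 fallen, and 3286 without the array of dam 13. In that fit Dcx also fell by 1.82 ± 0.13 (adjusted p = 7.28e-09), while over 24 arrays its change of -1.81 ± 0.95 was not called (adjusted p = 0.261).

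Of 38 ribosomal protein genes in undosed hippocampus 32 fell and 0 rose (camera adjusted p = 1.33e-26; adjusted p = 0.0131 with an estimated correlation), for example Rps24, which fell by 0.64 ± 0.08. Of 31 genes of immature and migrating neurons 13 fell and 0 rose (adjusted p = 1.3e-09; adjusted p = 0.00244 with an estimated correlation). Calcium signalling genes rose in 22 of 50 and synaptic vesicle genes in 13 of 33, with estimated-correlation adjusted p of 0.0131 and 0.0107. Myelin genes rose in 12 of 18 (adjusted p = 5.67e-11; adjusted p = 0.0713 with an estimated correlation), and meningeal genes fell in 6 of 19 (adjusted p = 8.46e-06; adjusted p = 0.0727 with an estimated correlation). Adjusted over the list alone these 6 lists had 34, 14, 24, 14, 12 and 11 called.

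In dosed hippocampus Mbp rose by 3.25 ± 0.27 (3 arrays per age, adjusted p = 8.93e-07), Klf9 by 1.41 ± 0.13 and Camk2a by 1.54 ± 0.34, while Reln fell by 0.59 ± 0.10. Limma called 1090 probe sets, with 594 risen and 496 fallen (403 and 228 with the values as deposited), and 2935 without the array of dam 13. Ribosomal protein genes fell in 26 of 38 and migrating neuron genes in 13 of 31, with 31 and 17 called when adjusted over the list alone and estimated-correlation adjusted p of 0.0234 and 5.77e-04. Dosed and undosed hippocampus shared 387 rises against 39 if independent and 347 falls against 37. Between undosed cerebellum and hippocampus 408 rises were shared against 107, and 235 falls against 67. Of the 1638 rises in cerebellum 60 were falls in hippocampus. Both tissues thus shared rises in Klf9, Mbp, Slc17a7 and Pvalb, while Syt4, a synaptotagmin, rose by 1.56 ± 0.13 in cerebellum and fell by 1.03 ± 0.13 in hippocampus.

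Cerebellum and hippocampus of undosed pups were compared to show what marks each tissue. At PND7 Pcp2, a Purkinje cell protein, was higher in cerebellum by 4.67 ± 0.11 (3 arrays per tissue, adjusted p = 9.33e-16), Pax6, a transcription factor of granule cells, by 3.78 ± 0.17, Cbln1, a synapse organiser, by 3.27 ± 0.22 and Calb1, a calcium buffer, by 2.21 ± 0.08. Crym, which binds thyroid hormone in the cell, was lower at -4.96 ± 0.20, Lhx2, a transcription factor of the forebrain, at -3.80 ± 0.18 and Nrgn, a calmodulin-binding protein of dendrites, at -3.39 ± 0.30. Limma called 3152 probe sets, 1607 higher and 1545 lower in cerebellum, and 5235 without the array of dam 13. Cell cycle genes were higher in 29 of 36 (camera adjusted p = 6.51e-19; adjusted p = 0.015 with an estimated correlation) and granule precursor genes in 10 of 12, while synaptic vesicle genes were lower in 21 of 33, with 33, 11 and 22 called in those directions when adjusted over the list alone. Genes of hippocampal neurons were lower in 8 of 15 (adjusted p = 2.35e-04; adjusted p = 0.0694 with an estimated correlation), and in 8 over the list alone.

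At PND14 Pcp2 was higher in cerebellum by 5.67 ± 0.11, Gabra6 by 4.14 ± 0.26 and Cbln1 by 4.31 ± 0.22 (adjusted p from 5.91e-17 to 1.04e-09, 3 arrays per tissue), while Crym was at -4.74 ± 0.20 and Ddn, a protein of dendrites, at -4.69 ± 0.24. Nsmf, which carries synaptic signals to the nucleus, was at -4.06 ± 0.83, or -2.33 ± 0.15 without the array of dam 13. Limma called 4596 probe sets, 2708 higher and 1888 lower, and 2843 and 2745 without that array. With the values as deposited the share of calls that were higher was 71.2% against 58.9%, and the median of all probe sets was 0.18 against 0.03. Purkinje genes were higher in 10 of 14 (adjusted p = 1.97e-08; adjusted p = 6.11e-04 with an estimated correlation), hippocampal neuron genes lower in 11 of 15 (adjusted p = 8.52e-06; adjusted p = 0.0584 with an estimated correlation) and ribosomal protein genes higher in 34 of 38 (adjusted p = 4.25e-11; adjusted p = 0.107 with an estimated correlation), with 10, 12 and 34 called in those directions over the list alone. The 2 ages shared 1318 probe sets higher in cerebellum against 418 if independent, and 947 lower against 280.

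**Figure D4:**
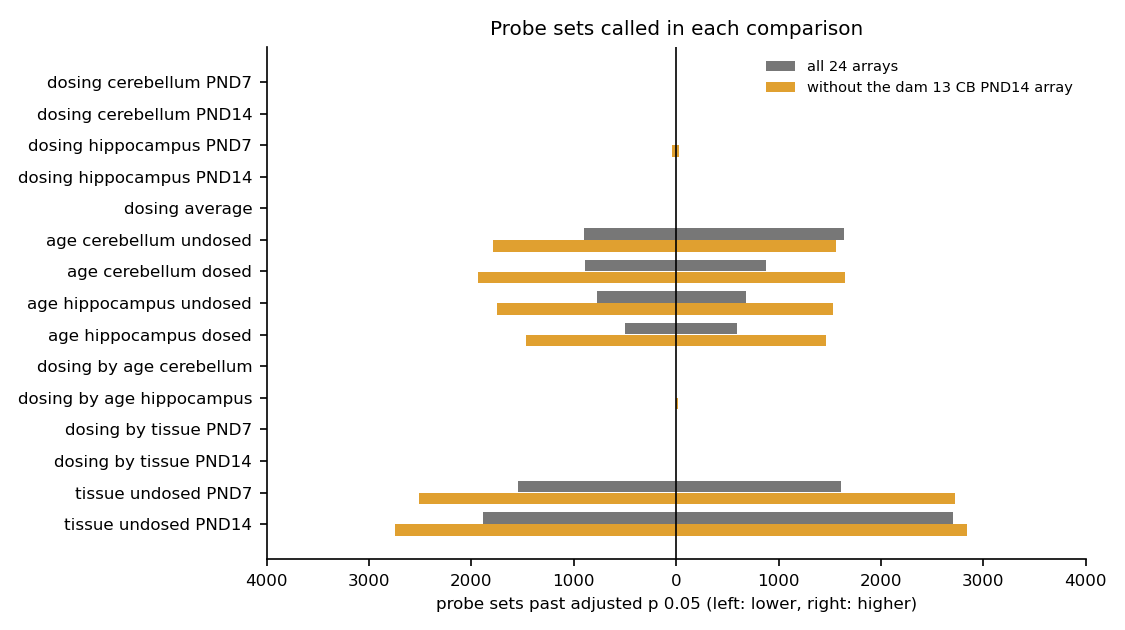
Number of probe sets called (adjusted p under 0.05) in each of the 15 comparisons, with lower calls to the left and higher calls to the right of 0, for all 24 arrays (grey) and without the array of dam 13 (orange). Dosing calls appear only in hippocampus without that array, 62 at PND7 and 14 for the difference between ages.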

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

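The 3 tests of the dam 13 array were chosen after the results had been seen. The tests of meningeal tissue, of the pup with high Xist and of other splits were written before their results. Most values given without the dam 13 array were also chosen after the results. The exception is counts and gene changes in single comparisons that include its group, where leaving out each replicate was planned. Groups hold 3 arrays, so no group was large enough for a test of single outlying samples.

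A difference of the dosing effect between ages passed in some fits and not in others. In hippocampus 14 probe sets were called for this difference without the array of dam 13, among them Dcn, a proteoglycan of connective tissue, and Slc25a27, a mitochondrial carrier of neurons, where the effect at PND14 exceeded that at PND7 by 0.85 ± 0.16 and 0.93 ± 0.15. With the 4 arrays of high Xist left out as well 0 of the 14 calls remained, and over 24 arrays limma called 0, with 517 at an unadjusted p under 0.05. As lists, meningeal genes (camera adjusted p = 0.000322) and ribosomal protein genes (0.00347) passed for a difference between ages in hippocampus. The effect on meningeal genes was less negative at PND14, and the median for ribosomal protein genes went from -0.053 at PND7 to 0.025 at PND14. With an estimated correlation these became 0.922 and 0.933. In cerebellum the effect on choroid plexus genes and on red cell genes was higher at PND14, both with an adjusted p of 0.0419 and of 0.917 with an estimated correlation. Of the 4 red cell genes in cerebellum 1 was called over the list alone, and of 10 choroid plexus genes 0. With the dam as a block the choroid plexus list gave 0.0611.

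The first pattern weighed is the array of dam 13 in undosed cerebellum at PND14. A mislabelled sample from these tissues and ages is argued against as the cause of its low r, since its highest r with any array was 0.659 and the lowest among the other 23 was 0.941, while a sample from elsewhere was not tested. Its centred profile had an r of 0.29 with both dosed and undosed cerebellum at PND14 against 0.114 for the next group, so its dosing label stays unchecked. Degraded RNA would raise the 3' over the 5' signal, and the actin difference was 0.38, below the 0.55 to 1.21 of the other arrays. The GAPDH difference was 0.61, within the 0.48 to 0.91 of the others. The median and lowest value of this array differ from those of the others, so these differences cannot settle its RNA quality. A fault of the array or of its values is consistent with the spike-in controls, of which 6 of 18 probe sets lay below all other arrays, while of 9 later probe sets for the same spikes 0 lay below and 7 above, as did 3 of the 9 older ones, and the kind of fault stays open.

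The second pattern is the lower connective tissue genes in dosed hippocampus at PND7. More or less meninges in the dissected tissue is a candidate explanation. Among the 12 hippocampal arrays the 36 lower calls outside the meningeal list followed the mean of that list within groups with a median r of 0.305, above all of 10000 random sets, whose median was -0.016 and 95th percentile 0.123. The 24 higher calls did not follow it, at -0.084. Random sets were drawn gene by gene, so calls that vary together for any reason could also lie outside their range. The mean of the meningeal list was 8.57 ± 0.16 in undosed and 8.11 ± 0.18 in dosed hippocampus at PND7 (log2, SD, n = 3). Abundant members such as Col1a2 differed too, at 9.90 ± 0.31 and 9.13 ± 0.41. An undosed pup with high Xist stays open as a source. Without the PND7 hippocampus array of dam 13 the median call kept 1.05 of its change (quartiles 1.01 and 1.12). With fewer arrays 17 of the 62 stayed called. The share could hardly have been low, because the calls were picked with that array included. A change carried by 1 of 3 undosed arrays would widen the spread and would rarely be called. A real effect of dosing on connective tissue or vessels was not tested apart from the dissection and stays open.

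All 10 splits of the 6 dams into 3 and 3 were fitted for each dosing comparison, too few for a share under 0.05. The real split gave 0 calls in each of the 9 dosing comparisons, so all 10 splits had to give at least as many and this decides nothing. The highest other was 3 for cerebellum at PND14 and 0 elsewhere. With that array of dam 13 left out the real split gave 62 for hippocampus at PND7 and 14 for its difference between ages, and 1 was the highest other in both. Splits of the arrays in the age and tissue comparisons are as few. The real split there gave 2537, 1771, 1452 and 1090 for age, with a highest other of 7, 0, 0 and 0, and 3152 and 4596 for tissue, with 0 and 645. Other splits there mix ages or tissues within a group, which widens its spread, so their low counts say little.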

How the results depend on the processing

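Leaving out the array of dam 13 was planned for single comparisons that include its group, as each replicate was left out in turn. For the other comparisons, the dosing average and the gene lists, fits without it were chosen after the data had been seen. So were fits that leave out other arrays with it, and the dam as a block for gene lists. The other alternatives were planned. The transforms log2(value + 1) and log2(value + 64) were not run because the values are already on a log scale.

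An intensity trend and a stricter filter kept all 15 counts of calls within 1.5 times. Without a filter dosing in hippocampus at PND7 gave 2 calls. With the values as deposited, age gave 925 calls in undosed and 631 in dosed hippocampus. With only the 12 arrays of a tissue, age gave 1106 and 881 in undosed and dosed cerebellum and 3305 and 2870 in undosed and dosed hippocampus, where the array of dam 13 no longer adds to the spread. Dosing in hippocampus at PND7 then gave 12 and its difference between ages 12, and with only the 6 arrays compared it gave 1. With the dam as a block the difference between ages in hippocampus gave 2 calls, the choroid plexus list lost its call for dosing by age in cerebellum (0.0611) and for tissue at PND7 (0.0607), and the thyroid hormone list for age in dosed hippocampus (0.0557) and the kinase list for tissue at PND7 (0.0686) lost theirs. The red cell list gained one for dosing by age in hippocampus (0.0164). The block changed no other count by more than 1.5 times and no other list call, and the correlation of arrays of one dam was 0.039.

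Without the array of dam 13 the counts became 62 for dosing in hippocampus at PND7, 14 for its difference between ages, 3590, 3286 and 2935 for age in dosed cerebellum, undosed hippocampus and dosed hippocampus, and 5235 for tissue at PND7. Leaving out the 4 arrays with high Xist as well gave 3 for dosing in hippocampus at PND7, 0 for its difference between ages and 1620, 3154 and 2393 for age in undosed cerebellum, dosed cerebellum and dosed hippocampus. Leaving out the PND14 arrays of dam 15 instead gave 247 for dosing in hippocampus at PND7, 10 for its difference between ages, 23 for dosing by tissue at PND7, 4016, 3745, 3903 and 3216 for age in undosed and dosed cerebellum and undosed and dosed hippocampus, and 5749 for tissue at PND7. The cause was not tested. Every fit in this paragraph used quantile normalized values, and none used the values as deposited.

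With each replicate left out in turn, dosing in cerebellum at PND14 gave 0 to 2563 calls. The 2329 and 2563 came without dam 1 and dam 7, when the array of dam 13 is 1 of 2 left. Dosing in hippocampus at PND7 gave 0 to 1 and its difference between ages 0 to 2. Age gave 1653 to 4619 in undosed and 1292 to 1539 in dosed cerebellum, 859 to 1050 in undosed and 608 to 965 in dosed hippocampus. Tissue gave 2596 to 2774 at PND7 and 3685 to 5777 at PND14. For age the counts beyond 1.5 times came without dam 1 at PND14 (4619), dam 7 at PND14 (4556) or dam 1 at PND7 (1653) in undosed cerebellum, without dam 1 at PND7 (859), dam 7 at PND14 (914) or dam 13 at PND14 (957) in undosed hippocampus, and without dam 18 at PND14 (608), dam 12 at PND14 (676) or dam 12 at PND7 (660) in dosed hippocampus. The other comparisons stayed at 0.

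Of 989 results for named genes 452 passed, and 338 of these stayed called in the same direction under every alternative in which their probe set was tested. The stricter filter, for example, kept probe sets for 858 of the 989. Fits that leave out other arrays together with that of dam 13 were not applied to named genes. With each replicate left out, changes with age in undosed cerebellum ran from -2.91 to 0.24 for Cox6c, -1.54 to 0.51 for Bhlhe41, -3.84 to 0.36 for Calm2, -1.66 to 0.30 for Hprt1, -3.18 to 0.36 for Ppp3cb, -0.69 to 0.98 for Ryr2 and -3.48 to 0.40 for Cox8a. Differences between tissues at PND14 ran from -1.83 to 0.33 for Rpsa, -1.24 to 1.81 for Dcx, -3.00 to 0.31 for Rps29 and -2.08 to 0.36 for Rps15a, and every highest value is the one without the array of dam 13. The granule precursor list for dosing in cerebellum at PND14 turned lower without it (0.0289). With fry the thyroid hormone list at PND7 (7.25e-05) and the astrocyte (0.015) and migrating neuron (0.0095) lists at PND14 turned in the comparison of tissues. Of 115 list calls by camera 76 were lost with an estimated correlation. Without the array of dam 13, 12 list calls were lost and 17 gained, and 88 of 645 results for named genes gained a call. Low signal over background limits genes near the filter, such as Lum in dosed hippocampus at PND7, and Cyp1a1, which was not tested.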

Other observations

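The test of the pace of development was chosen after the results had been seen, and the values of single pups were looked up after them.

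A hypothesis was that dosing slows the age change. Each array was placed on an index from the 500 probe sets with the largest age change among those called in the same direction in both undosed and dosed pups, where 0 is the mean of the 2 PND7 groups and 1 the mean of the 2 PND14 groups. The cerebellum PND14 array of dam 13 was left out. For dosing slows the age change in cerebellum, the dosed minus undosed difference at PND14 was 0.006 (SE 0.065, 3 against 2 pups, exact permutation p = 0.7). In hippocampus it was -0.012 (SE 0.108, 3 against 3, exact permutation p = 0.9), and the smallest p that 3 against 2 or 3 can give is 0.1. Without dam 15 the differences were 0.087 in hippocampus and 0.036 in cerebellum, so the sign in hippocampus rests on 1 pup. At PND7 dosed pups were ahead by 0.04 (SE 0.033) in cerebellum and 0.057 (SE 0.04) in hippocampus, with exact permutation p of 0.4 and 0.2. Taking probe sets called in both dosing groups leaves out any whose age change dosing removed. These values neither show nor exclude a slower pace, and a small delay could go unseen behind these SE.

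The dosed pup of dam 15 stood apart at PND14 in hippocampus. Its hippocampal index was 0.796, where the other 5 hippocampal arrays of that age had 0.946 to 1.128, while its cerebellar index of 0.943 lay within the 0.94 to 1.056 of the others. Its Mbp in hippocampus was 11.39, and its Gabra6 in cerebellum 9.14, the lowest values of their groups. Hbb in this pup was 12.8 in hippocampus and 13.37 in cerebellum, the highest of their groups.

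Xist, the RNA of the inactive X chromosome in females, was high in 4 arrays of 2 undosed pups that the labels call male. It was 10.55 and 9.73 in cerebellum and hippocampus of the PND7 pup of dam 13, and 10.72 and 9.08 in those of the PND14 pup of dam 1. The other arrays were at most 4.31, apart from the cerebellum PND14 array of dam 13 at 6.59.

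Ttr, which choroid plexus makes in large amounts, varied widely within some groups and little within others. In undosed hippocampus at PND7 it ranged from 8.84 to 12.82 and in dosed cerebellum at PND14 from 7.07 to 13.37 (log2, 3 arrays each), while in undosed cerebellum at PND7 it ranged from 12.82 to 13.29 and in dosed hippocampus at PND14 from 8.41 to 8.94.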
